A study of Mus musculus with 16 samples.

How the data were processed

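Chromatin-associated RNA was sequenced from E14TG2a mouse embryonic stem cells, per the labels kept in LIF at 1000 U per ml, PD0325901 at 1 µM and CHIR99021 at 3 µM. The cells ectopically expressed full-length or IDR-deleted KDM4A, KDM4B, KDM6A or KDM6B, with 2 libraries for each of the 8 groups. Per the labels, rRNA was depleted before libraries were made with a stranded kit.

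The deposited gene table holds raw read counts per gene, made by the authors, per the file headers, with featureCounts 2.0.3 at a mapping quality of at least 30 from HISAT2 alignments to GRCm39 extended by spike-in sequences. The deposited repeat table holds raw read counts per single repeat copy from the same program and alignments. Per the file headers each read of a pair was counted and strand was ignored, and reads that matched several places or several features were not given to any. The submitters' processing notes name GRCm39, HISAT2, SAMtools, Picard, MACS2 and featureCounts without versions. All values in the deposited tables are whole numbers, and no column is pooled.

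The gene table has 56941 gene entries, 92 ERCC RNAs and 2 controls of an RNA methylation kit, which drew 0 reads. ERCC RNAs, 0.587% to 1.54% of gene reads by group, were kept out of library sizes and tests, and the labels do not mention them. Symbols and gene classes came from GENCODE M21 by Ensembl identifier (51948 genes, 4993 without), and positions are those of the deposited table on GRCm39. The repeat table has 4929385 copies in 61 classes or families, 2665980 of them outside the spans of the genes in the gene table. Its labels go down to the family, so the subfamily sums that were planned became family sums, and planned groups such as single endogenous retroviruses were not analysed here. A read in an exon that holds a repeat can enter each table, so the tables overlap.

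Libraries held 32739117 to 54890756 gene reads. For a group, 3 reads stood for the floor, below which no reads cannot be told from few. That is the 95% level for independent reads. Genes without reads in a group were given as lower bounds against that floor. Genes with 1 to 3 reads were given as a ratio with a 95% counting interval. Each read of a pair was counted, so reads are not independent, and the bounds may be too high and the intervals too narrow. Between the 2 libraries of a group, log2 CPM correlated at 0.980 to 0.988. The median chi-square per gene was 1.28 to 1.83, where independent reads, which these are not, give 0.455.

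Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10), TMM scaling, 1 robust quasi-likelihood fit of all 16 libraries with 8 group means and 8 residual degrees of freedom, and a test of IDR-deleted minus full-length for each demethylase. P-values were adjusted by Benjamini-Hochberg at 0.05, and the standard error is the log2 fold change divided by the root of F. The difference between the deletion effects of KDM4A and KDM4B, and of KDM6A and KDM6B, was tested in the same fit. For 2 against 2 libraries alone an exact p cannot go below 0.33. Lists of at least 5 genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera sets a list against the other genes, so its up and down calls are relative to these under every scaling. The 29 lists, fixed without sight of the data, were 2-cell-stage, naive pluripotency, formative and primed epiblast, Hox, Polycomb-bound developmental regulators, germline, imprinted, Zfp, clustered protocadherin, interferon-stimulated, p53 target, ATF4 and unfolded-protein-response, heat-shock, hypoxia-induced, cholesterol synthesis, ERK-induced, H3K9 and heterochromatin machinery, Polycomb and MLL complex, cell cycle, histone, ribosomal protein, mitochondrially encoded, chromatin-retained noncoding RNA, small structured RNA, fibroblast, primitive endoderm, trophectoderm, mesendoderm and neural genes. Besides the adjustment over all genes, p-values of each list's members were adjusted over the list alone.

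Repeat families (60 after the filter) were tested like genes with TMM over families. Single copies with at least 5 reads in at least 2 libraries were tested with the effective library sizes of the genes and a trended dispersion, 716086 in all after filterByExpr. The share of reads on repeats and 8 related measures were compared by exact permutation stratified by demethylase, with 1296 labelings and a smallest p of 0.00154.

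Genes were named by rule: the 4 demethylases and, in each contrast, the 8 largest rises and 8 largest falls past the threshold with at least 1 CPM in the higher group, both deleted libraries beyond both full-length ones and a symbol that is not a gene model. Added were, from each list up to 4 members past the threshold with the smallest p, or else the most highly expressed member. Named families were the 5 largest rises and falls past the threshold with at least 100 reads on average. Some items that these rules take are not reported here.

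Alternatives tried were DESeq2 1.42.0, median-ratio scaling, ERCC scaling, other filters, fits of 4 libraries, replicate blocks, thinning to the smallest library, each library left out in turn, an estimated correlation per list, fry, scaling of repeats by the gene table or over copies, copies outside genes only, families without their largest copy and genes without chromosome 6. The scripts used data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

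The pipeline was tested on simulated data made from these libraries with 200 genes changed 1.5-, 2- or 4-fold. By edgeR it recovered 50.7%, 79.1% and 90.9% in KDM4A (6 false calls among 30140 genes), 37.3%, 59.7% and 92.4% in KDM4B (8 among 30124), 50.7%, 56.7% and 92.4% in KDM6A (10 among 30120) and 49.3%, 65.7% and 92.4% in KDM6B (6 among 30075). DESeq2 recovered the same shares in KDM4A with 11 false calls, and the test of a difference 37.3%, 59.7% and 83.3% with 4. For single copies the shares were 1.49%, 26.9% and 83.3% (2 false calls among 38993), and for families 100% at each size (2 of 2). Those copies were scaled by TMM over copies, so the copy test with the sizes of the genes was not itself checked. A list shifted by 0.5 came out at rank 1 of 29, with 1 other list called. Simulated genes varied independently, so this does not probe the correlation between genes of a list. Far fewer genes and copies changed in the simulations than were called in the data, so these rates may not carry over.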

Results

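The series measured RNA bound to chromatin in E14TG2a mouse embryonic stem cells grown with LIF, the MEK inhibitor PD0325901 and the GSK3 inhibitor CHIR99021. The cells ectopically expressed a histone demethylase, either full-length or without its intrinsically disordered region (IDR): KDM4A and KDM4B, which act on methylated H3K9 and H3K36, or KDM6A (UTX) and KDM6B, which act on methylated H3K27. The sample titles call the deletion del-cIDR and other labels del-IDR, without saying which residues were removed or whether the region was the same in every demethylase. There were 8 groups of 2 libraries, 16 in all, and every group carried a construct, so each contrast sets IDR-deleted against full-length protein. Libraries held 32739117 to 54890756 reads over genes and 20313223 to 47548396 over repeats, and 34227 to 38085 genes were detected in each. In what follows, "rose" and "fell" mean higher or lower in the IDR-deleted group at adjusted p under 0.05 (edgeR), values are log2 fold changes ± standard error, and group values are CPM ± SD with n = 2. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples. Bounds and intervals for rare RNAs cover counting error only. They take reads as independent although each read of a pair was counted, so they may be too strong.

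The 4 target genes came first. Kdm6a (ENSMUSG00000037369, chromosome X, 18028814 to 18146175) reached 429 ± 11.3 CPM in the 4 libraries with a KDM6A construct and 117 ± 22.4 CPM in the other 12, a 3.67-fold excess. Kdm4a (ENSMUSG00000033326, chromosome 4, 117994154 to 118037240) stood at 254 ± 49.3 CPM in its own libraries against 210 ± 37.9 CPM elsewhere (1.21-fold). For Kdm4b (ENSMUSG00000024201, chromosome 17, 56633062 to 56709870) the values were 92.2 ± 7.59 and 89.5 ± 9.29 CPM (1.03-fold), and for Kdm6b (ENSMUSG00000018476, chromosome 11, 69289334 to 69304501) 88.2 ± 8.20 and 74.2 ± 3.97 CPM (1.19-fold). Only the KDM6A libraries thus stood out clearly by reads of their own gene. For the other 3 genes the counts do not tell reads of a construct from endogenous ones, so expression of those constructs is not shown here, and the changes of Kdm4a, Kdm4b and Kdm6b below are of all reads counted on these genes. By multidimensional scaling, the first dimension held 39.5% of the variance and set the KDM6B groups (1.56 to 1.71) and IDR-deleted KDM4A (1.66 and 1.67) apart from the remaining groups, with IDR-deleted KDM4B near the middle.

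**Figure D1:**
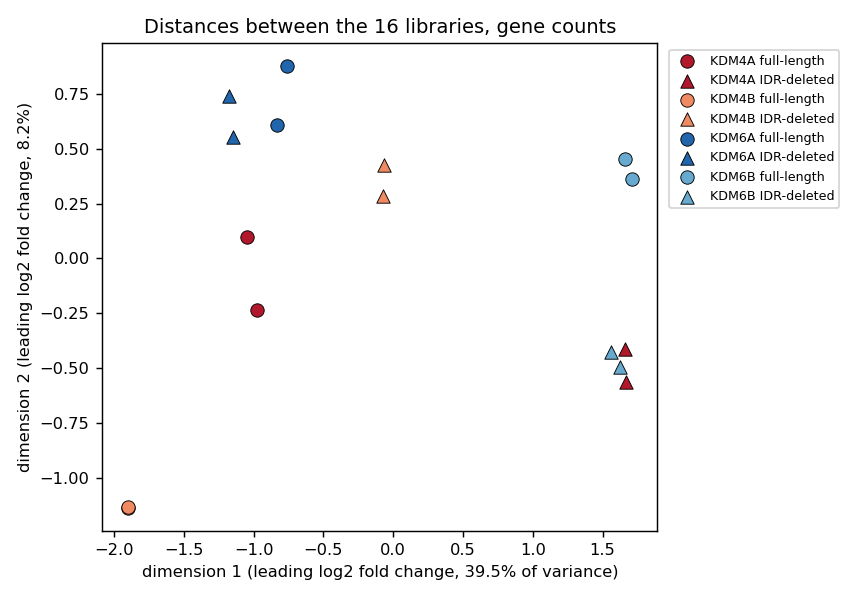
Each point is 1 of the 16 libraries, coloured by group, placed by the first (39.5% of variance) and second (8.20%) dimension of multidimensional scaling of log2 CPM.

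Of 31057 genes tested, 15672 (50.5%) changed on deletion in KDM4A, 11240 (36.2%) in KDM4B, 5265 (16.95%) in KDM6A and 6406 (20.6%) in KDM6B. The rises and falls numbered 7638 and 8034, 5784 and 5456, 2578 and 2687, and 3072 and 3334 in that order. Groups did not overlap at all for 73.2%, 66.8%, 53.6% and 58.0% of genes, where chance alone gives 33.3%. All of these are relative to the median gene: scaling by the ERCC RNAs moved the median by -0.65, -0.19, -0.21 and -0.38, and then only 7.61%, 25.1%, 5.84% and 4.74% of the changed genes were rises, in place of 48.7%, 51.5%, 49.0% and 48.0%. The near-even splits also tipped over under other settings: for example in KDM4A without replicate 2 of the deleted group (7046 up and 6757 down), in KDM4B with median-ratio scaling (5420 and 5857), DESeq2 (5085 and 5520), thinned counts (5377 and 5520) and a fit of 4 libraries (5605 and 5837), in KDM6A with median-ratio scaling (2707 and 2606), DESeq2 (2713 and 2545) and no filter (2642 and 2598), and in KDM6B with a fit of 4 libraries (3653 and 3414). Reads were counted on either strand, so antisense and overlapping genes are uncertain, and so are single members of near-identical families such as Zscan4, olfactory and vomeronasal receptors, Iglc, protocadherins and histones.

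The KDM4A contrast asks how chromatin-bound RNA differs when KDM4A lacks its IDR. Kdm4a itself rose, from 211 ± 8.16 to 296 ± 6.24 CPM (0.49 ± 0.04, adjusted p = 3.5e-12), but was lower with ERCC scaling (-0.17, adjusted p = 0.0144). Kdm6a fell (-0.50 ± 0.04, adjusted p = 4.2e-13), and Kdm4b (-0.13 ± 0.07) and Kdm6b (0.00 ± 0.06) did not pass, except with ERCC scaling (-0.79 and -0.65, adjusted p = 1.9e-14 and 6.8e-13). The largest named rise was Zic1 (ENSMUSG00000032368, chromosome 9, 91240111 to 91247863), a neural transcription factor, by 4.06 ± 0.67. Sox9 (ENSMUSG00000000567, chromosome 11, 112673050 to 112678586), a regulator of cartilage and gonad, stood at 4.93 ± 0.142 against 0.311 ± 0.153 CPM (4.001 ± 0.33). The synaptic C1ql2 (3.10 ± 0.62), the skeletal factor Pax9 (3.06 ± 0.32) and the WNT regulator Amer2 (3.04 ± 0.36) followed. Inka1 (2.94 ± 0.27) and the odorant receptors Olfr1353 (2.94 ± 0.66) and Olfr1351 (2.92 ± 0.22) completed the 8. The largest falls were receptor and immunoglobulin genes. No read of Iglc1 (ENSMUSG00000105906, chromosome 16, 18880368 to 18880821), Vmn2r78, Iglc4, Olfr364-ps1 or Olfr873 was counted in the deleted group. With reads taken as independent, this puts the falls at least at 45.9-fold, 39.0-fold, 24.99-fold, 22.9-fold and 22.7-fold. Iglc3 fell 86.7-fold (15.3 to 3450.5) and Olfr1430-ps1 72.6-fold (19.8 to 603), each with at most 3 reads left, and Olfr365 went from 9.20 ± 0.393 to 0.103 ± 0.145 CPM. Of 310 olfactory and vomeronasal receptor genes, 166 fell and 6 rose (median -1.99, or -1.51 with the 65 genes that had a group without reads at their bound). Changes of at least 2-fold leaned down, with 1716 rises and 3798 falls. Among all changed genes, noncoding and rarely transcribed classes leaned down: 1481 of 5035 long noncoding genes, 1008 of 3945 pseudogenes and 806 of 2008 TEC genes fell, and 391, 356 and 176 rose. Among 17020 other protein-coding genes, 6561 rose and 4023 fell.

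Early-embryo genes fell together. Zscan4d went from 71.8 ± 1.05 to 13.2 ± 1.07 CPM (-2.44 ± 0.08), and its cluster mate Zscan4e fell by a similar step (-2.12 ± 0.07). For the 2-cell-stage list the count was: of 32 genes, 1 rose, 26 fell and 5 did not pass (2 and 27 adjusted over the list alone), at a median of -1.44 (adjusted p = 1.6e-10). Clustered protocadherins, which label neurons, followed, among them Pcdhgb5 (-2.12 ± 0.09) and Pcdhga8 (-2.25 ± 0.11). Of 36 genes, 1 rose, 22 fell and 13 did not pass (1 and 22 adjusted over the list alone), at a median of -1.69 (adjusted p = 1.0e-08). Chromatin-retained long noncoding RNAs fell as a list, with the imprinting RNA Kcnq1ot1 dropping from 2033 ± 49.8 to 631.9 ± 17.04 CPM (-1.69 ± 0.03), the paraspeckle RNA Neat1 (-1.19 ± 0.03) and the Xist antagonist Tsix (-1.68 ± 0.05). Of 25 genes, 8 rose, 12 fell and 5 did not pass (8 and 12 adjusted over the list alone), at a median of -0.33 (adjusted p = 0.0315, and adjusted p = 0.444 with an estimated correlation).

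Several lists of developmental genes were called up. Polycomb-bound regulators outside the Hox clusters rose, such as the endoderm factor Gata6 (2.37 ± 0.24) and the limb factor Tbx4 (1.58 ± 0.14). Of 60 genes, 38 rose, 2 fell and 20 did not pass (39 and 2 adjusted over the list alone), at a median of 1.29 (adjusted p = 3.4e-07). Trophectoderm markers included Gata2 (2.38 ± 0.18) and Tfap2c, a placental factor (40.7 ± 2.37 against 14.1 ± 0.239 CPM; 1.53 ± 0.09). Of 15 genes, 13 rose, 0 fell and 2 did not pass (13 and 0 adjusted over the list alone), at a median of 1.43 (adjusted p = 1.0e-05). Primitive endoderm markers included the growth factor receptor Pdgfra (1.72 ± 0.15) and the collagen Col4a2 (0.96 ± 0.05). Of 21 genes, 12 rose, 4 fell and 5 did not pass (12 and 4 adjusted over the list alone), at a median of 0.96 (adjusted p = 0.00375, and adjusted p = 0.0618 with an estimated correlation). Neural markers rose as well, Map2 (1.06 ± 0.14) against a fall of Stmn2 (-0.58 ± 0.07). Of 18 genes, 10 rose, 1 fell and 7 did not pass (10 and 1 adjusted over the list alone), at a median of 0.82 (adjusted p = 0.0115). Fibroblast markers were led by the matrix protease Mmp2 (1.87 ± 0.09). Of 14 genes, 7 rose, 2 fell and 5 did not pass (7 and 2 adjusted over the list alone), at a median of 0.66 (adjusted p = 0.0313, and adjusted p = 0.0687 with an estimated correlation). Formative and primed epiblast genes split between the DNA methyltransferase Dnmt3b (0.82 ± 0.06) and a fall of Otx2 (-0.999 ± 0.09). Of 21 genes, 11 rose, 4 fell and 6 did not pass (11 and 6 adjusted over the list alone), at a median of 0.41 (adjusted p = 0.0434, and adjusted p = 0.0763 with an estimated correlation). Germline genes silenced by DNA methylation leaned up, with the piRNA helicase Mov10l1 (1.02 ± 0.08) and the meiotic Meioc (0.81 ± 0.07). Of 35 genes, 25 rose, 3 fell and 7 did not pass (25 and 3 adjusted over the list alone), at a median of 0.60 (adjusted p = 1.8e-05). Imprinted genes included Peg10 (1.48 ± 0.05) and Peg3 (1.40 ± 0.04). Of 37 genes, 22 rose, 6 fell and 9 did not pass (22 and 6 adjusted over the list alone), at a median of 0.41 (adjusted p = 0.00492, and adjusted p = 0.0673 with an estimated correlation).

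Several lists of growth and stress genes were called up as well. Ribosomal protein genes rose as a list, Rplp1 by 1.18 ± 0.04. Of 79 genes, 69 rose, 4 fell and 6 did not pass (70 and 4 adjusted over the list alone), at a median of 0.56 (adjusted p = 5.7e-16). Heat-shock genes included the chaperones Hsp90aa1 (1.16 ± 0.03) and Hspa1b (2.07 ± 0.12). Of 18 genes, 15 rose, 1 fell and 2 did not pass (15 and 2 adjusted over the list alone), at a median of 0.53 (adjusted p = 7.9e-06). Cholesterol synthesis genes included squalene synthase Fdft1 (1.14 ± 0.05). Of 22 genes, 17 rose, 2 fell and 3 did not pass (17 and 2 adjusted over the list alone), at a median of 0.58 (adjusted p = 1.0e-05). ERK-induced genes included Jun (1.502 ± 0.10) and Ccn1 (1.496 ± 0.06). Of 29 genes, 17 rose, 4 fell and 8 did not pass (17 and 4 adjusted over the list alone), at a median of 0.70 (adjusted p = 5.5e-04). The p53 targets included the p53 ligase Mdm2 (507 ± 13.9 against 228 ± 2.14 CPM; 1.15 ± 0.04). Of 28 genes, 18 rose, 4 fell and 6 did not pass (18 and 4 adjusted over the list alone), at a median of 0.51 (adjusted p = 1.1e-04). Hypoxia-induced genes included the angiogenic factor Vegfa (0.94 ± 0.04). Of 28 genes, 19 rose, 1 fell and 8 did not pass (20 and 1 adjusted over the list alone), at a median of 0.31 (adjusted p = 2.3e-05). Mitotic genes included the kinetochore protein Cenpf (1.02 ± 0.03). Of 28 genes, 21 rose, 2 fell and 5 did not pass (21 and 2 adjusted over the list alone), at a median of 0.36 (adjusted p = 4.1e-06). Polycomb and MLL complex genes included the MLL complex member Rbbp5 (0.63 ± 0.04), and the list turned to the other direction under ERCC scaling (adjusted p = 0.238). Of 43 genes, 25 rose, 9 fell and 9 did not pass (25 and 9 adjusted over the list alone), at a median of 0.17 (adjusted p = 0.00397, and adjusted p = 0.119 with an estimated correlation). Mitochondrially encoded genes rose, mt-Co1 by 0.80 ± 0.03. Of 13 genes, 11 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone), at a median of 0.50 (adjusted p = 4.0e-04, and adjusted p = 0.183 with an estimated correlation).

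The other 9 lists were not called in KDM4A. Of naive pluripotency genes 6 rose, 14 fell and 4 did not pass (adjusted p = 0.0613): Tbx3 fell (-1.09 ± 0.04) and Tfcp2l1 rose (0.67 ± 0.03). H3K9 and heterochromatin machinery (adjusted p = 0.167) held a fall of the methyltransferase Suv39h1 (-1.14 ± 0.07) and a rise of Mphosph8 (1.07 ± 0.05), and ATF4 and unfolded-protein-response genes (adjusted p = 0.518) a fall of the transporter Slc7a3 (-2.50 ± 0.10) and a rise of the stress factor Ddit3 (1.24 ± 0.07). Small structured RNAs gave adjusted p = 0.0656, Zfp genes 0.707, and the Hox, interferon, histone and mesendoderm lists 0.976 each. For the Hox, ATF4, histone and mesendoderm lists the median, the mean and the test did not share a sign, since members moved both ways: Hoxb9 fell (-1.96 ± 0.11) while Hoxa10 rose (1.78 ± 0.28), and the Nodal antagonist Lefty2 fell (-2.11 ± 0.11) while Eomes rose (1.17 ± 0.13). In all, camera called 20 lists, 17 up and 3 down (14 and 6 with ERCC scaling), of which 13 (11 up and 2 down) were still called with the correlation between genes estimated per list. The 2-cell-stage, protocadherin, Polycomb-bound, germline, p53, heat-shock, hypoxia, cholesterol, ERK, mitotic, ribosomal, trophectoderm and neural lists were those 13. Of 127 named genes that changed, 9 rises went below 0 under ERCC scaling, 5 of them far enough to pass as falls, and 18 genes no longer passed, among them Tfcp2l1, Meioc and Rbbp5.

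The KDM4B contrast asks the same of KDM4B. Kdm4b (88.9 ± 4.90 against 95.5 ± 10.3 CPM; -0.10 ± 0.07, adjusted p = 0.239) and Kdm6b (-0.04 ± 0.06) did not pass, except with ERCC scaling (-0.29 and -0.23, adjusted p = 8.7e-04 and 0.00605). Kdm4a rose (0.20 ± 0.04, adjusted p = 3.2e-04; 0.01 and adjusted p = 0.901 with ERCC scaling) and Kdm6a fell (-0.33 ± 0.04, adjusted p = 2.3e-08). The largest named rise was the lipid hydroxylase Fa2h (ENSMUSG00000033579, chromosome 8, 112071767 to 112120456, 3.33 ± 0.58). The inner-ear protein Otog (10.2 ± 1.14 against 1.26 ± 0.0773 CPM, 3.00 ± 0.14), Hs3st3a1 (2.96 ± 0.62) and Ccer2 (2.82 ± 0.48) followed. The X-linked Xlr3a (2.78 ± 0.11) and Xlr5a (2.72 ± 0.41), Trim40 (2.69 ± 0.34) and Ccdc172 (2.67 ± 0.13) came next. Among the falls, the cytochrome Cyp2j7 (ENSMUSG00000081362, chromosome 4, 96083434 to 96124896) had no read left, a loss of at least 81.3-fold with reads taken as independent. Olfr505-ps1 fell 162-fold (44.4 to 1344), Olfr361 95.4-fold (26.0 to 795) and Olfr362 69.6-fold (18.8 to 582), each with at most 3 reads left. With as few reads, Cyp2j7-ps1 fell 66.5-fold (17.97 to 556) and Olfr235 58.5-fold (15.8 to 490.03). Olfr364-ps1 (-5.76 ± 0.51) and the protease inhibitor Serpina3m (-5.63 ± 0.32) completed the set. Receptor genes fell here too, 125 of 310 against 13 rises (median -1.17), as did 693 of 5035 long noncoding and 427 of 2008 TEC genes against 508 and 152 rises, while 4701 other protein-coding genes rose and 3464 fell.

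Early-embryo genes fell, with Zscan4d (25.5 ± 0.857 against 88.5 ± 1.00 CPM, -1.79 ± 0.07) in front. Among 32 2-cell-stage genes, 0 rose, 19 fell and 13 did not pass (0 and 20 adjusted over the list alone), at a median of -0.78 (adjusted p = 1.8e-10). Protocadherins such as Pcdhgb6 (-1.15 ± 0.12) leaned down. Of 36 genes, 0 rose, 16 fell and 20 did not pass (0 and 16 adjusted over the list alone), at a median of -0.67 (adjusted p = 4.9e-05). So did histone genes, for example Hist1h1b (-0.65 ± 0.05). Of 65 genes, 2 rose, 22 fell and 41 did not pass (2 and 22 adjusted over the list alone), at a median of -0.25 (adjusted p = 0.00160). Naive pluripotency genes fell as a list, including Klf5 (-0.67 ± 0.05) and Spp1 (-0.69 ± 0.04). Of 24 genes, 4 rose, 17 fell and 3 did not pass (4 and 17 adjusted over the list alone), at a median of -0.28 (adjusted p = 2.2e-04, and adjusted p = 0.148 with an estimated correlation). Chromatin-retained noncoding RNAs included Kcnq1ot1 (-0.84 ± 0.03), Xist (-1.11 ± 0.05) and a rise of Platr14 (1.54 ± 0.06). Of 25 genes, 2 rose, 14 fell and 9 did not pass (2 and 14 adjusted over the list alone), at a median of -0.20 (adjusted p = 1.4e-04, and adjusted p = 0.196 with an estimated correlation). The H3K9 and heterochromatin list included the SETDB1 partner Atf7ip (216 ± 0.0954 against 478 ± 4.90 CPM; -1.14 ± 0.04) and the heterochromatin protein Cbx5 (-0.52 ± 0.04). Of 26 genes, 4 rose, 13 fell and 9 did not pass (4 and 13 adjusted over the list alone), at a median of -0.13 (adjusted p = 0.00180, and adjusted p = 0.0633 with an estimated correlation).

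The lists called up held extraembryonic, Polycomb-bound, germline, ribosomal, mitochondrial, mitotic and ATF4 genes. Trophectoderm markers included Esx1 (1.68 ± 0.23) and Eomes (1.23 ± 0.14). Of 15 genes, 12 rose, 1 fell and 2 did not pass (12 and 1 adjusted over the list alone), at a median of 1.06 (adjusted p = 3.7e-05). Primitive endoderm markers included the endocytic adaptor Dab2 (1.10 ± 0.10). Of 21 genes, 11 rose, 1 fell and 9 did not pass (13 and 1 adjusted over the list alone), at a median of 0.65 (adjusted p = 2.2e-04). Polycomb-bound regulators included Gata6 (1.58 ± 0.26). Of 60 genes, 17 rose, 2 fell and 41 did not pass (17 and 2 adjusted over the list alone), at a median of 0.40 (adjusted p = 0.00956). Germline genes included Meioc (40.7 ± 1.07 against 13.8 ± 0.339 CPM; 1.56 ± 0.07) and the cohesin subunit Smc1b (0.96 ± 0.06). Of 35 genes, 20 rose, 4 fell and 11 did not pass (22 and 4 adjusted over the list alone), at a median of 0.74 (adjusted p = 4.6e-06). Ribosomal protein genes rose as a list, Rplp1 by 0.81 ± 0.04. Of 79 genes, 65 rose, 0 fell and 14 did not pass (68 and 2 adjusted over the list alone), at a median of 0.33 (adjusted p = 2.2e-16). Mitochondrially encoded genes rose too, mt-Nd5 by 0.72 ± 0.05. Of 13 genes, 10 rose, 0 fell and 3 did not pass (11 and 0 adjusted over the list alone), at a median of 0.46 (adjusted p = 1.7e-04, and adjusted p = 0.196 with an estimated correlation). Mitotic genes included the kinesin Kif23 (0.53 ± 0.04). Of 28 genes, 19 rose, 1 fell and 8 did not pass (20 and 1 adjusted over the list alone), at a median of 0.18 (adjusted p = 2.2e-04, and adjusted p = 0.0650 with an estimated correlation). ATF4 genes included the glutathione enzyme Chac1 (1.57 ± 0.09). Of 31 genes, 18 rose, 4 fell and 9 did not pass (18 and 5 adjusted over the list alone), at a median of 0.20 (adjusted p = 0.00235, and adjusted p = 0.124 with an estimated correlation). Camera called 14 lists, 8 up and 6 down, and with ERCC scaling 6 up and 8 down. With an estimated correlation the 2-cell-stage, protocadherin, histone, trophectoderm, primitive endoderm, Polycomb-bound, germline and ribosomal lists, 8 in all, were still called. Adjusted p of the 15 lists not called ran from 0.0919 (Polycomb and MLL genes) to 0.996 (mesendoderm, where Lefty2 fell, -2.45 ± 0.10). The heat-shock and mesendoderm lists had a median, mean and test of unlike sign. None of 10 small structured RNAs changed by edgeR with TMM, where 2 were higher at unadjusted p and DESeq2 called 2. The neural list was not called, yet Stmn2 (-1.16 ± 0.07) and Elavl3 (-0.995 ± 0.09) fell.

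KDM4B was also the contrast in which chromosome 6 stood apart. The median of its 736 well-expressed genes was -0.37, against -0.09 to 0.08 on the other autosomes, and 83.0% of them were lower. Of 1630 tested genes there, 787 changed and 687 of these fell. Without chromosome 6, 10424 of 29449 genes changed, 5388 up and 5036 down, a split about as even as with it. The gene lists were not tested again without it, so list members on this chromosome may carry its shift. In the KDM6A contrast the same chromosome had a median of -0.15 (others -0.01 to 0.05) and 75.3% of its genes were lower. Chromosome 8 stood apart to a lesser degree. In KDM4B it was the lowest of the other autosomes (-0.09, 60.5% of genes lower), the rest being at 0.01 to 0.08. In KDM6B it was the highest autosome (0.07, 34.7% of genes lower), before chromosome 19 (0.03).

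**Figure D2:**
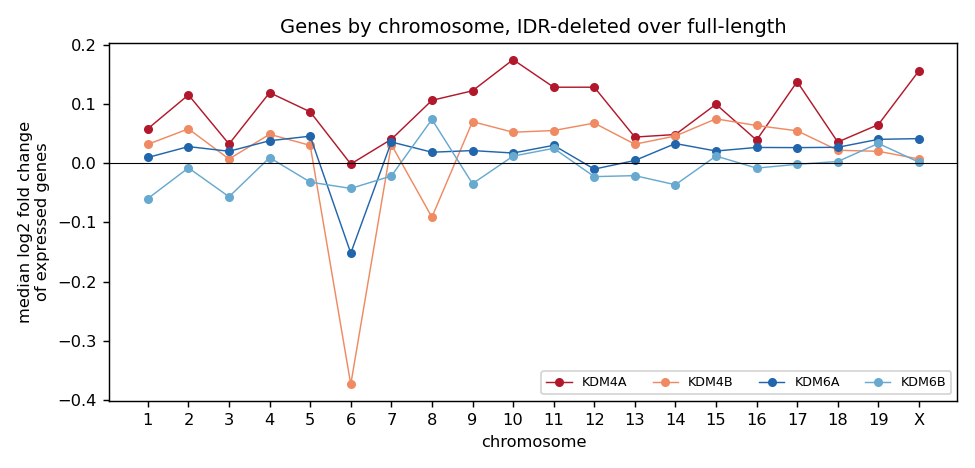
Median log2 fold change of expressed genes (vertical axis) on each chromosome (horizontal axis) in the 4 contrasts. Chromosome 6 reached -0.37 in KDM4B and -0.15 in KDM6A.

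The KDM6A contrast asks what loss of the IDR of UTX changes. Kdm6a did not pass (425 ± 14.1 against 433 ± 11.3 CPM; -0.03 ± 0.04, adjusted p = 0.766), except with ERCC scaling (-0.24, adjusted p = 0.00114). Kdm4a (-0.17 ± 0.04, adjusted p = 0.00591) and Kdm4b (-0.27 ± 0.07, adjusted p = 0.00450) fell, and Kdm6b did not pass (0.08 ± 0.06). Effects were the smallest of the 4 contrasts: 397 genes changed at least 2-fold, 89 up and 308 down. The largest named rise, Toporsl (ENSMUSG00000028314, chromosome 4, 52596274 to 52612430, 1.89 ± 0.56), was followed by Olfr1129 (1.88 ± 0.59), Olfr365 (1.67 ± 0.23), Vmn2r78 (1.60 ± 0.33) and Olfr838-ps1 (1.42 ± 0.23). Olfr1128 (1.41 ± 0.25), the cytochrome Cyp2b23 (1.39 ± 0.14) and Vmn2r79 (1.38 ± 0.13) came next. Of the 310 receptor genes, 21 rose and 4 fell (median 0.14, or 0.13 at the bounds). Falls were led by Rgl3, a Ras effector (ENSMUSG00000040146, chromosome 9, 21880007 to 21900742, -2.08 ± 0.32), and the opioid receptor Oprk1 (-2.07 ± 0.41). The neural catenin Ctnna2 (-1.99 ± 0.42), the cell-cycle inhibitor Cdkn1c (-1.99 ± 0.33) and Adssl1 (-1.88 ± 0.27) fell next. Nwd2 (-1.87 ± 0.43) and Rgs17 (-1.77 ± 0.46) were among the other falls.

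Mitochondrially encoded genes rose in KDM6A, mt-Nd5 from 167 ± 1.98 to 329 ± 9.85 CPM (0.98 ± 0.05). Of 13 genes, 11 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone), at a median of 0.79 (adjusted p = 1.1e-11, and adjusted p = 0.0726 with an estimated correlation). Hypoxia-induced genes fell, with the kinase Pdk1 (-0.91 ± 0.06), the glycolytic enzyme Gpi1 (-0.65 ± 0.04) and Vegfa (-0.51 ± 0.04). Of 28 genes, 0 rose, 14 fell and 14 did not pass (0 and 14 adjusted over the list alone), at a median of -0.25 (adjusted p = 9.3e-10, and adjusted p = 0.0726 with an estimated correlation). Histone genes such as Hist1h3a (-0.57 ± 0.14) leaned down. Of 65 genes, 0 rose, 8 fell and 57 did not pass (0 and 7 adjusted over the list alone), at a median of -0.12 (adjusted p = 0.00599, and adjusted p = 0.0726 with an estimated correlation). Among 2-cell-stage genes Zscan4a fell (-0.40 ± 0.08) and Pramel7 rose (0.75 ± 0.11). Of 32 genes, 2 rose, 13 fell and 17 did not pass (2 and 14 adjusted over the list alone), at a median of -0.17 (adjusted p = 0.0386, and adjusted p = 0.162 with an estimated correlation). Rises marked formative epiblast genes, with the let-7 inhibitor Lin28a (0.98 ± 0.11). Of 21 genes, 10 rose, 0 fell and 11 did not pass (12 and 0 adjusted over the list alone), at a median of 0.16 (adjusted p = 0.00489, and adjusted p = 0.0726 with an estimated correlation). Ribosomal protein genes followed, Rpl27a by 0.34 ± 0.04. Of 79 genes, 24 rose, 0 fell and 55 did not pass (31 and 0 adjusted over the list alone), at a median of 0.11 (adjusted p = 1.2e-07, and adjusted p = 0.132 with an estimated correlation). Heat-shock genes included the chaperonin Hspd1 (0.42 ± 0.04). Of 18 genes, 7 rose, 3 fell and 8 did not pass (8 and 3 adjusted over the list alone), at a median of 0.11 (adjusted p = 0.0424, and adjusted p = 0.242 with an estimated correlation). None of these 7 calls, 4 up and 3 down, held with an estimated correlation, and ERCC scaling gave 2 up and 5 down. Outside the called lists, Kcnq1ot1 rose (0.51 ± 0.03) and Neat1 fell (-0.56 ± 0.03), the meiotic regulator Stra8 fell (-1.08 ± 0.12), and Setd1b rose (0.75 ± 0.07). Adjusted p of the 22 uncalled lists ran from 0.0532 (fibroblast markers) to 0.958 (germline genes), and for the germline, p53, primitive endoderm and mesendoderm lists the median, mean and test disagreed in sign. None of 36 protocadherins changed by edgeR with TMM, where 3 passed at unadjusted p (2 higher and 1 lower) and DESeq2 called 0, while with ERCC scaling the named Pcdhga12 was lower (-0.27, adjusted p = 0.00353). For Polycomb-bound regulators, 2 of which had a group without reads, the median was -0.12, or -0.15 at the bounds (2 rose, 2 fell and 56 did not pass).

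The KDM6B contrast asks the same of KDM6B. Kdm6b rose slightly (94.7 ± 2.38 against 81.6 ± 5.05 CPM; 0.21 ± 0.06, adjusted p = 0.00818), but was lower with ERCC scaling (-0.16, adjusted p = 0.0461), and Kdm4a (-0.04 ± 0.04), Kdm4b (0.01 ± 0.07) and Kdm6a (-0.06 ± 0.04) did not pass, except with that scaling (-0.42, -0.37 and -0.44, adjusted p = 3.1e-08, 2.4e-05 and 8.8e-09). Among the largest rises were the anion exchanger Slc26a4 (3.41 ± 0.67) and the retinal factor Pou4f2 (ENSMUSG00000031688, chromosome 8, 79159639 to 79163274, 3.13 ± 0.41). Nsg2 (2.99 ± 0.42), the histamine receptor Hrh3 (2.66 ± 0.62) and the synaptotagmin Syt6 (2.61 ± 0.49) were others. Beside them rose the transporter Slco1c1 (10.3 ± 0.167 against 1.30 ± 0.213 CPM, 2.98 ± 0.09). Mylk2 (2.64 ± 0.41) and Shisal2b (2.28 ± 0.50) closed the set. Falls were led by tyrosine aminotransferase Tat (ENSMUSG00000001670, chromosome 8, 110717069 to 110726435, -2.90 ± 0.32), the glutamate receptor Grm8 (-2.18 ± 0.28) and the cadherin Cdh20 (-2.17 ± 0.44). The imprinted RNA H19 (-1.92 ± 0.29), AW495222 (-1.74 ± 0.35), Anxa3 (-1.47 ± 0.23), Slc3a1 (-1.47 ± 0.32) and Hspe1-ps3 (-1.43 ± 0.29) followed. TEC genes fell (643 of 2008, against 25 rises), as did 556 long noncoding genes against 158 rises, while 2633 other protein-coding genes rose and 1718 fell. Receptor genes moved little, 22 up and 9 down (median 0.00, or -0.08 with the 70 genes that had a group without reads at their bound).

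Neural markers rose, with Stmn2 (43.7 ± 0.493 against 16.2 ± 0.202 CPM; 1.43 ± 0.07), Elavl3 (0.94 ± 0.09) and the neurofilament Nefl (0.88 ± 0.13). Of 18 genes, 8 rose, 0 fell and 10 did not pass (8 and 0 adjusted over the list alone), at a median of 0.52 (adjusted p = 5.2e-06). Formative epiblast genes rose without a fall, among them Dnmt3a (0.57 ± 0.05) and Lin28b (0.76 ± 0.08). Of 21 genes, 9 rose, 0 fell and 12 did not pass (9 and 0 adjusted over the list alone), at a median of 0.32 (adjusted p = 7.4e-06). Histone genes leaned up, for example Hist1h4h (0.49 ± 0.08). Of 65 genes, 18 rose, 0 fell and 47 did not pass (19 and 0 adjusted over the list alone), at a median of 0.29 (adjusted p = 9.0e-09). Protocadherins did as well, for example Pcdhga3 (0.54 ± 0.11). Of 36 genes, 5 rose, 0 fell and 31 did not pass (5 and 0 adjusted over the list alone), at a median of 0.26 (adjusted p = 0.00546), the median being 0.25 at the bounds. Ribosomal protein genes rose as a list, Rps16 by 0.57 ± 0.05. Of 79 genes, 71 rose, 0 fell and 8 did not pass (75 and 0 adjusted over the list alone), at a median of 0.37 (adjusted p = 1.1e-31). Mitochondrially encoded genes rose with them, mt-Co1 by 0.58 ± 0.03. Of 13 genes, 10 rose, 0 fell and 3 did not pass (11 and 0 adjusted over the list alone), at a median of 0.42 (adjusted p = 5.2e-06, and adjusted p = 0.159 with an estimated correlation). Heat-shock genes such as Hspb1 (0.38 ± 0.07) were called up. Of 18 genes, 8 rose, 0 fell and 10 did not pass (9 and 1 adjusted over the list alone), at a median of 0.17 (adjusted p = 0.00277, and adjusted p = 0.123 with an estimated correlation). ATF4 genes such as Creld2 (0.38 ± 0.06) were called up too. Of 31 genes, 8 rose, 1 fell and 22 did not pass (9 and 1 adjusted over the list alone), at a median of 0.13 (adjusted p = 0.00415, and adjusted p = 0.159 with an estimated correlation). The heat-shock and ATF4 lists turned to the other direction under ERCC scaling (adjusted p = 0.608 and 0.106). Of the 8 calls, all up, the neural, formative, histone, protocadherin and ribosomal lists, 5 in all, held with an estimated correlation. With ERCC scaling camera called 11 lists up and 8 down relative to the other genes, at a median of -0.38 over all genes. A list called up there need not have risen against the ERCC RNAs. With TMM scaling, fry, which tests a list by itself, called 14 up and 4 down, and it was not run with ERCC scaling. Elsewhere the laminin Lama1 (-0.73 ± 0.04), the ETS factor Etv4 (-1.01 ± 0.10), Peg10 (-0.76 ± 0.05) and the germ-cell RNA-binding protein Dazl (-0.94 ± 0.10) fell, and Bst2, an interferon-induced gene, rose (1.14 ± 0.25). Adjusted p of the 21 uncalled lists ran from 0.0541 (interferon genes) to 0.968 (p53 targets). The 2-cell-stage, imprinted, Zfp, p53 and primitive endoderm lists had a median, mean and test of unlike sign. None of 10 small structured RNAs changed by edgeR with TMM, and 0 did at unadjusted p or by DESeq2. Of 121 named genes that changed, 23 rises went below 0 under ERCC scaling and 8 of them passed as falls, against 0 of 124 below 0 in KDM4B and 4 of 118 in KDM6A (0 passed). Named genes that no longer passed with it numbered 46 in KDM6B, among them Pcdhga3, Hist1h4h, Hspb1 and Creld2, 28 in KDM6A, among them Rpl27a, and 5 in KDM4B.

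**Figure D3:**
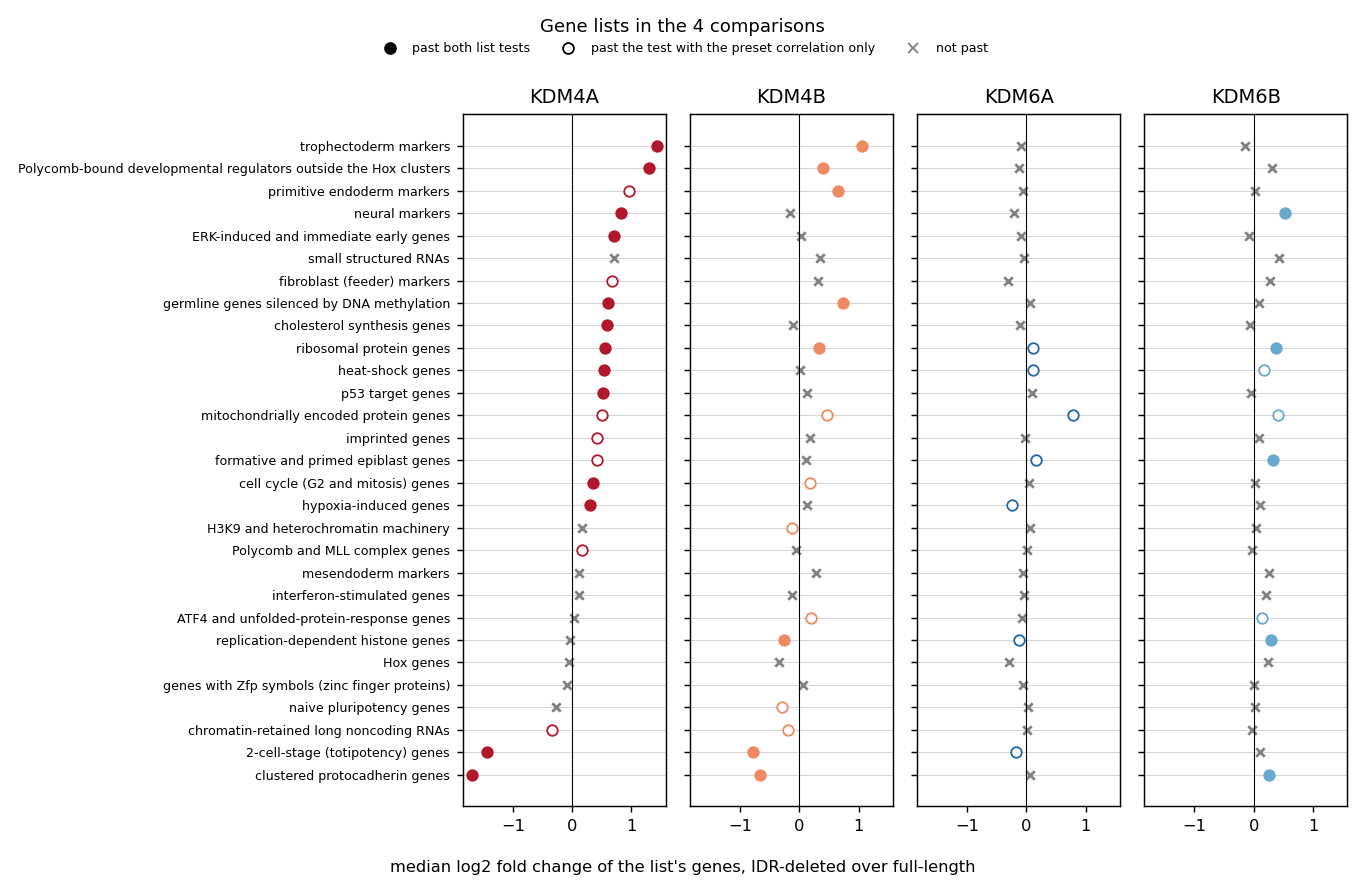
Median log2 fold change of each fixed gene list in the 4 contrasts, from 2-cell-stage genes (-1.44 in KDM4A) to trophectoderm markers (1.43 in KDM4A). Filled points passed camera with the preset and the estimated correlation, open points only with the preset one, and crosses neither; the horizontal axis is the median.

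Did the deletions act alike? Fold changes of KDM4A and KDM4B ran together (r = 0.472, rank correlation 0.484), and of 8248 genes that changed in both, 86.8% moved the same way: 3720 rose in both contrasts, where 1422 are expected by chance, and 3437 fell in both (1411 expected). The KDM6A changes ran against those of KDM4A (r = -0.190; 4054 shared genes, 23.0% in the same direction) and KDM4B (r = -0.180; 3409 shared, 20.9%). KDM6B showed little linear relation to KDM4A (r = 0.0159, rank 0.157), although 66.6% of 4528 shared genes moved alike (1469 rises, 756 expected; 1547 falls, 862 expected), and little to KDM4B (-0.0245; 54.8% of 3455) or KDM6A (-0.0235; 39.9% of 1962). These are all 6 pairs, and genes are not independent replicates, so the correlations carry no p-value. The expected counts take every gene as equally likely to be called, so overlap can exceed them without likeness. KDM6A and KDM6B shared 478 rises (255 expected) and 305 falls (288 expected), and KDM4B and KDM6B 952 (572) and 942 (586). Below expectation were KDM6A with KDM4A, at 605 rises (634) and 326 falls (695), and with KDM4B, at 350 (480) and 363 (472). The effect of the deletion differed between KDM4A and KDM4B at 9653 genes (4795 with a more positive and 4858 with a more negative effect in KDM4A) and between KDM6A and KDM6B at 6768 (3430 and 3338) by the edgeR test of the difference. In those tests camera called 18 lists (16 up and 2 down) between KDM4A and KDM4B, 11 of them (9 up and 2 down) with an estimated correlation, and 8 lists (1 up and 7 down) between KDM6A and KDM6B, 3 of them (all down) with it. Protocadherins, for example, fell further with KDM4A than with KDM4B (median of the difference -1.03, adjusted p = 1.4e-07), and cholesterol genes were higher (0.66, adjusted p = 1.6e-09).

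Many repeats carry methylated H3K9, and the share of reads on repeats differed between the groups. This share is repeat counts over the sum of repeat and gene counts. Reads counted on neither are left out, and reads counted on both enter both counts. Repeats took 38.1% ± 0.306 against 44.8% ± 0.383 of reads (mean ± SD, IDR-deleted against full-length, n = 2) in KDM4A, 45.6% ± 0.291 against 47.8% ± 0.140 in KDM4B, 48.5% ± 0.514 against 47.7% ± 0.153 in KDM6A and 33.4% ± 0.0243 against 37.2% ± 0.318 in KDM6B. The mean difference over the 4 contrasts was -3.01 points (stratified permutation p = 0.00926, adjusted p = 0.0119 over 9 measures; higher in 1 of 4). For copies outside genes it was -1.07 points (permutation p = 0.0679). Per 100 gene reads the difference was -1.40 reads on copies outside genes (permutation p = 0.0679) and -7.09 on copies inside them (permutation p = 0.00772). The share over all repeats and both measures outside genes include 1 hAT-Tip100 copy of chromosome 17 with 25717741 reads over all libraries. They also include 1 simple-repeat copy nearby with 4140593. Outside genes the hAT-Tip100 and simple-repeat families rose in KDM4A (1.45 and 1.21), and the measures were not computed without these copies. Moving the other way, ERCC RNAs (0.21 points, adjusted p = 0.00347), ribosomal protein mRNA (0.31 points) and mitochondrial mRNA (0.05 points) were higher in percent of gene reads in 4 of 4 contrasts, each at the smallest p the permutation can give (0.00154). Signal recognition particle RNA was higher in percent of repeat reads in 3 of 4 (0.11 points, permutation p = 0.00926). Ribosomal protein mRNA made 1.44% ± 0.0198 against 1.12% ± 0.0248 of gene reads in KDM4A and 2.73% ± 0.0196 against 2.13% ± 0.0322 in KDM6B.

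Counts summed over 60 repeat families changed for 34 families in KDM4A (15 up and 19 down), 14 in KDM4B (6 and 8), 0 in KDM6A and 14 in KDM6B (12 and 2). The KDM6B split turned to 3 up and 9 down outside genes and was 14 and 8 without the largest copies; in KDM4A it turned with median-ratio scaling and with DESeq2 (20 and 17 each). In KDM6A edgeR gave 3 families at unadjusted p and DESeq2 called 3. Scaled by the gene table instead, the counts were 47 (4 and 43), 35 (1 and 34), 11 (10 and 1) and 41 (1 and 40). In KDM4A rises were rRNA (1.80 ± 0.52, adjusted p = 0.0173), srpRNA (1.34 ± 0.12), hAT-Tip100 (0.91 ± 0.21), Satellite/Y (0.90 ± 0.06) and simple repeats (0.33 ± 0.03). Falls were I-Jockey (-0.57 ± 0.22), Helitron (-0.46 ± 0.07), tRNA-RTE (-0.42 ± 0.08), RTE-BovB (-0.29 ± 0.09) and L1 (-0.29 ± 0.02). A single copy on chromosome 17 (40153889 to 40154054) held 98.1% of hAT-Tip100 reads, and without it the family gave -0.15. The largest copies of simple repeats (40155501 to 40155535) and rRNA (40157244 to 40159092) lay close by on that chromosome. Reads of a single locus may thus enter all of these rises, although simple repeats still gave 0.29 without their largest copy (adjusted p = 4.5e-13). A single copy likewise held 50.9% of Satellite/Y reads, and without it the family gave 0.02 (adjusted p = 0.8075). Without their largest copy rRNA (1.42, adjusted p = 0.0640) and I-Jockey (-0.29, adjusted p = 0.589) did not pass, though most of the rRNA rise remained. By the gene table's scaling simple repeats did not pass (0.03, adjusted p = 0.0969). Outside genes srpRNA (-0.23) and Satellite/Y (-0.17) reversed. There rRNA (1.64, adjusted p = 0.0502) and Helitron (-0.46, adjusted p = 0.196) kept about their size but did not pass, and tRNA-RTE (-0.28, adjusted p = 0.649) did not pass either. In a fit of 4 libraries rRNA and I-Jockey did not pass either. In KDM4B L1-Tx1 (0.47 ± 0.15) and srpRNA (0.42 ± 0.11) rose and the falls included Satellite (-0.21 ± 0.03), L1 (-0.17 ± 0.02) and ERVL (-0.17 ± 0.02). Without its largest copy, which held 51.0% of its reads, L1-Tx1 gave 0.05 (adjusted p = 0.889). L1-Tx1 did not pass by the gene table's scaling either (0.30, adjusted p = 0.0914), nor outside genes, where its rise was larger (1.29, adjusted p = 0.0602). The srpRNA rise kept most of its size without the largest copy (0.38, adjusted p = 0.337) and was 0.26 outside genes (adjusted p = 0.132), but passed in neither. Every KDM4B rise ended when full-length replicate 1 or deleted replicate 2 was left out (0 up and 5 down each). Its smaller rises of Satellite/Y, 7SL and B2 reversed when scaled by the gene table (-0.0219, -0.0420 and -0.11). In KDM6B rises included srpRNA (0.81 ± 0.12, adjusted p = 0.000934; -0.20 outside genes), tRNA (0.41 ± 0.08) and ERV1 (0.33 ± 0.03; -0.00285 by the gene table), and the falls were PiggyBac (-0.27 ± 0.08) and Kolobok (-0.19 ± 0.07; 0.00216 outside genes). Outside genes tRNA (0.69, adjusted p = 0.129) and PiggyBac (-0.50, adjusted p = 0.402) did not pass although their changes were larger, and ERV1 (0.08, adjusted p = 0.206) did not pass with a smaller one. By the gene table's scaling tRNA did not pass (0.08, adjusted p = 0.507), nor did srpRNA and PiggyBac in a fit of 4 libraries.

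Among 716086 single copies tested, 139000 changed in KDM4A (23194 up and 115806 down), 33546 in KDM4B (7442 and 26104), 909 in KDM6A (654 and 255) and 29826 in KDM6B (2291 and 27535). With TMM over copies the splits were 46130 and 64533, 11355 and 17096, 405 and 309, and 4678 and 2444. Copies of ERVL elements of at least 5 kb, 614 in number, fell nearly as a block: 599 in KDM4A (median -1.28; -0.94 by TMM) and 580 in KDM4B (-0.89; -0.76), against 0 in KDM6A (0.14) and 25 in KDM6B (-0.25; 0.10 by TMM). Of 11344 L1 copies of at least 5 kb, 4526 fell and 51 rose in KDM4A (median -0.78; -0.45 by TMM), 1609 and 35 in KDM4B (-0.48; -0.34 by TMM) and 6 and 20 in KDM6A (0.04; -0.01 by TMM). In KDM6B 335 rose and 131 fell (0.27; 0.62 by TMM), and shorter L1 copies had a median of -0.39, but only -0.05 by TMM. Long ERV1 copies, 215 in number, had medians of -0.89 in KDM4A (-0.56 by TMM; 64 fell and 2 rose), -0.72 in KDM4B (39 and 8) and 0.35 in KDM6B (0.70 by TMM; 23 rose and 1 fell). Single copies with large changes were a B2 element on chromosome 4 (83347342 to 83347531; 3.76 ± 0.17) and an L1 element on chromosome 2 (37083422 to 37089310; -7.14 ± 0.29) in KDM4A. That L1 copy fell in KDM4B as well (-5.07 ± 0.18), next to one on chromosome 7 (108194283 to 108200459; -5.40 ± 0.18). In KDM6A an ERVK copy on chromosome 7 (86736608 to 86738668) rose by 1.46 ± 0.16, and in KDM6B an L1 copy on chromosome 6 (141516723 to 141517310) rose by 2.89 ± 0.19.

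**Figure D4:**
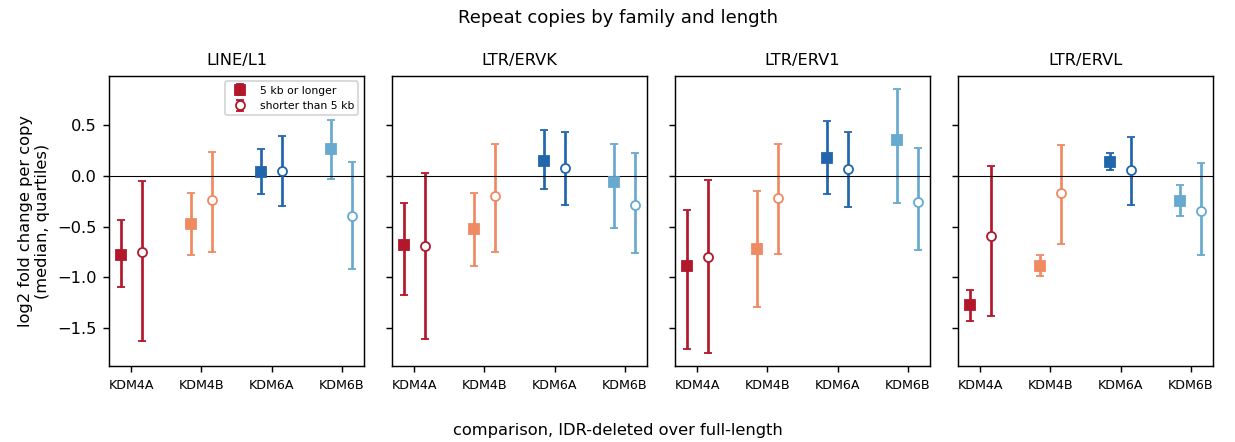
Median log2 fold change of single repeat copies by family and length in the 4 contrasts, with sizes from the gene table. ERVL copies of at least 5 kb reached -1.28 in KDM4A and -0.25 in KDM6B, the latter 0.10 with TMM over copies.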

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

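Of the tests of explanations in this part, only that of a mislabelled sample was written down before its value was computed; the others are tests chosen only after the result was seen. The gene lists, contrasts and most settings were fixed before the data were examined; ERCC scaling, families without their largest copy, genes without chromosome 6 and correlations with libraries left out were added later.

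Several results were singled out because the deletion had unlike effects in related demethylases. The effect differed between KDM4A and KDM4B at 9653 genes and between KDM6A and KDM6B at 6768 genes (edgeR test of the difference). As medians of the difference in log2 fold change, KDM4A minus KDM4B, the lists that also held with an estimated correlation were 2-cell-stage genes (-0.56), protocadherins (-1.03), formative epiblast genes (0.27), Polycomb-bound regulators (0.85), p53 targets (0.30), heat-shock genes (0.60), cholesterol synthesis (0.66), ERK-induced genes (0.45), H3K9 and heterochromatin machinery (0.26), Polycomb and MLL complexes (0.25) and neural markers (0.94). KDM6A minus KDM6B gave hypoxia-induced genes (-0.36), histone genes (-0.43) and neural markers (-0.70). The ERCC RNAs were singled out because no planned analysis used them: their share of gene reads was 0.21 points higher in the deleted groups, in 4 of 4 contrasts.

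Repeat reads fell against gene reads more with the KDM4A deletion than with any other, and 3 explanations were weighed. A larger part of mature, spliced RNA, which dilutes other reads, cannot be told apart from other causes: copies outside genes fell further than those inside by -0.70 in median, but copies in exons, which spliced RNA carries, would fall less anyway. Scaling by the gene table was tested with TMM over copies, where copies outside genes had a median of -0.70 (-1.03 by the gene table) and those inside -0.00134. Copies inside genes were 83.5% of all copies tested and so set that scaling themselves. The -0.70 thus repeats the difference between outside and inside, and the test cannot tell whether scaling made the fall that both share. The further fall of copies outside genes does not come from scaling, which moves all copies of a library alike. That the deletion itself lowers transcription outside genes remains possible, with 2 libraries per group and no label on whether they are separate cultures. Further cultures of each construct would test it.

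KDM4A deletion, and KDM4B deletion to a lesser degree, moved genes in the way that full-length KDM6B differs from full-length KDM6A (r = 0.621 and 0.451 across genes), and for KDM4A again 3 explanations were weighed. A shared rise of mature RNA would make the KDM4A and KDM6B deletions resemble each other, and they did so in part: r was 0.0159 and the rank correlation 0.157, yet 66.6% of the genes changed in both moved the same way, so this cannot be told apart from other causes. For a KDM6B sample under a KDM4A label, fewer differing genes than the 5265 of the KDM6A contrast were predicted. Instead 9359 genes differed from the nearer KDM6B group and 10528 from the other, so the libraries do not repeat the KDM6B ones. The KDM6B groups themselves differed at 6406 genes. A separate KDM6B culture under that label is therefore not excluded, since it is unknown how far such cultures would differ. A state of the cultures other than the deletion cannot be told apart from an effect of the deletion, because each group has 2 libraries of unknown independence.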

How the results depend on the processing

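ERCC scaling, added later, put 9, 0, 4 and 23 named rises below 0 in KDM4A, KDM4B, KDM6A and KDM6B (5, 0, 0 and 8 passed as falls) and 0 falls above it. Under the other settings 0 of the 490 calls on named genes reversed, while a call weakened in 101 comparisons with a library left out and in 13 under another setting. The causes of the following shifts were not tested except where stated. Genes that changed at least 2-fold numbered 5514, 2591, 397 and 914 for KDM4A, KDM4B, KDM6A and KDM6B. Without a fold limit, ERCC scaling gave 13954 changed genes in KDM6B, against 6406 with TMM. Lists called with an estimated correlation were 13, 8, 0 (8 at unadjusted p) and 5; fry called 23 in KDM4B, 16 in KDM6A and 18 in KDM6B, and ERCC scaling 19 in KDM6B (11 up and 8 down). Under ERCC scaling the Polycomb and MLL list in KDM4A (adjusted p = 0.238) and the ATF4 (0.106) and heat-shock (0.608) lists in KDM6B reversed. For families, copies outside genes gave 22 in KDM4A, the gene table's scaling gave 35 in KDM4B, 11 in KDM6A and 41 in KDM6B, DESeq2 25 in KDM4B and 3 in KDM6A, a fit of 4 libraries 2 in KDM6A, and families without their largest copy 22 in KDM6B. Of the named families only, those reversed outside genes were srpRNA (-0.23) and Satellite/Y (-0.17) in KDM4A, Kolobok in KDM4B (0.0686), and srpRNA (-0.20) and Kolobok (0.00216) in KDM6B. By the gene table they were Satellite/Y (-0.0219), 7SL (-0.0420) and B2 (-0.11) in KDM4B and Unknown (-0.00347), ERV1 (-0.00285) and Gypsy (-0.0132) in KDM6B, and without the largest copy hAT-Tip100 in KDM4A (-0.15), Satellite/Y in KDM4B (-0.0909) and Kolobok in KDM6B (0.0777). Copies outside genes that changed numbered 37765, 13066, 371 and 1377, a stricter filter (minimum count 30) gave 1470 in KDM6A, TMM over copies 7122 in KDM6B and a fit of 4 libraries 15538 in KDM6B. The repeat share of copies outside genes differed by -1.07 points. Among genes of at least 1 CPM the correlations were 0.621 for KDM4A with KDM4B, -0.351 for KDM4A with KDM6A, 0.114 for KDM4A with KDM6B, -0.308 for KDM4B with KDM6A and -0.0695 for KDM6A with KDM6B.

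Replicate numbers were not taken as a pairing: deviations of the numbered replicates correlated at 0.103 to 0.172 among the KDM4A, KDM4B and KDM6A groups and at -0.00260 to 0.0338 with KDM6B. As a hint only, a replicate block within each demethylase gave 16120, 12136, 6432 and 7651 genes, 2 families in KDM6A and 1750 copies in KDM6A, and a block common to all groups 16057, 11908, 6055 and 7291 genes.

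With each library left out in turn, a group falls to 1 library, the filter loosens and that lone sample is assumed to vary like the others. Genes then ranged over 13589 to 13803, 8908 to 8989, 3484 to 3950 and 4078 to 4930, and the tests of a difference over 8188 to 8753 (KDM4A with KDM4B) and 5422 to 6058 (KDM6A with KDM6B). Counts moved over 1.5-fold without full-length replicate 1 of KDM6A (3484), and without full-length replicate 1 (4078), deleted replicate 1 (4125) or deleted replicate 2 (4242) of KDM6B. Families ranged over 27 to 32, 5 to 10, 0 to 1 and 10 to 16, moving over 1.5-fold in KDM4B without full-length replicate 1 (5), full-length replicate 2 (9) or deleted replicate 2 (5) and in KDM6A without full-length replicate 1 (1). Copies ranged over 82028 to 96387, 15478 to 17407, 236 to 334 and 10737 to 17957, moving over 1.5-fold for every library left out but full-length replicate 1 of KDM4A (without full-length replicate 2, deleted 1 and deleted 2: 90079, 82028 and 90747). Lists ranged over 19 to 22, 14 to 15, 4 to 6 (4 without deleted replicate 1) and 8 to 9, the repeat share over -3.15 to -2.87 points, where 1 against 1 per stratum cannot pass the threshold, and the 6 correlations over 0.329 to 0.388 (KDM4A with KDM4B), -0.150 to -0.1001 (KDM4A with KDM6A), -0.0578 to 0.0654 (KDM4A with KDM6B), -0.138 to -0.116 (KDM4B with KDM6A), -0.0545 to 0.0274 (KDM4B with KDM6B) and -0.0392 to 0.0164 (KDM6A with KDM6B).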

Other observations

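Of the tests in this part, those of repeat reads on chromosome 6 and of L1 copies near receptor genes were written down before their values were computed, and the rest are tests chosen only after the result was seen.

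Some single repeat copies changed strongly, and a few of them lay close together. In KDM6B, 4 of the 5 named rises of single copies lay within 141516723 to 141534835 of chromosome 6, with an L1 copy at 2.89 ± 0.19. In KDM4A an ERVK copy on chromosome 3 (129551694 to 129557143) fell by 5.64 ± 0.21, and an L1 copy of chromosome 16 (18947803 to 18950442) by 5.02 ± 0.21. An ERV1 copy of chromosome 10 (26803398 to 26810944) fell in KDM4B (-5.33 ± 0.19), where an ERVK copy of chromosome 3 (97423650 to 97426315) rose by 2.83 ± 0.18. Long ERVK copies (1136 of at least 5 kb) had medians of -0.68 in KDM4A, -0.52 in KDM4B, 0.15 in KDM6A and -0.06 in KDM6B, or -0.35, -0.39, 0.0982 and 0.29 with TMM over copies, so the sign in KDM6B depends on the scaling.

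Chromosome 6 was lower along most of its length in the KDM4B contrast, and the shift was already visible in single groups: against all libraries, its genes stood at 0.21 and 0.20 in the 2 full-length KDM4B libraries, -0.14 and -0.12 in the IDR-deleted ones, -0.10 and -0.10 in IDR-deleted KDM6A, and 0.06 and 0.04 in full-length KDM6A. A few strong genes do not account for it, since 83.0% of expressed genes were lower. For a fall of repeat reads, no larger fall of copies outside genes on this chromosome was predicted, yet they fell further than on other autosomes (-0.63 against -0.22, a difference of -0.42). That test cannot decide, since a general fall would touch every chromosome and a fall of repeat reads on this one would give such values too. A difference in chromosome 6 copy number between the cell populations is a hypothesis that cannot be told apart from other causes: the highest of 15 stretches of 10 Mb, at the start of the chromosome, had a median of -0.10 ± 0.16 over 22 genes, too wide a spread to say whether it shares the fall of the rest (-0.24 to -0.48). Counting chromosomes, or sequencing DNA of the same cells, would test it.

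Olfactory and vomeronasal receptor genes could be lower because reads of long L1 copies run into them. Within 20 kb of an L1 copy of at least 5 kb, 56.5% of 161 receptor genes were lower in KDM4A against 50.3% of 149 farther away (difference 6.19 ± 5.66 points), and 44.7% against 35.6% in KDM4B (9.15 ± 5.54 points). The spread keeps this explanation open, and other genes showed a similar step (9.92 ± 0.84 and 6.39 ± 0.75 points). These spreads are binomial standard errors that take genes as independent, and they are too small where neighbouring genes move together. Strand-specific counts of the L1 copies and receptor exons would separate the explanations.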
